A study of Homo sapiens
Rattus norvegicus and Homo sapiens with 10 samples.

How the data were processed

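The series measured RNA by sequencing in xenografts of U251N, an established human glioblastoma cell line, grown in the brains of athymic RNU/RNU rats, which lack the T cells that would reject a human graft. Per the labels, 3 primary tumours were taken without ablation and 3 recurrent tumours grew back after laser interstitial thermal therapy (LITT), in which a laser fibre heats a tumour under magnetic resonance imaging. The other 4 libraries were 3 tumour-free control brains, described as 1 failed graft (control replicate 1) and 2 procedural controls, and 1 in vitro culture of the line, described as an outside reference. Groups were taken from the treatment label of each sample, and replicates were numbered in the order of their records, so that no number pairs samples across groups. The labels do not say in words that each library came from its own animal. If some shared an animal, the p-values would measure in part technical spread.

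Per the labels' protocols, tumour tissue was dissected from frozen brain slices, total RNA was purified on silica columns without a separate DNase step, and strand-specific libraries were made with a ribosomal-RNA depletion kit for small RNA inputs and read as pairs on an Illumina NextSeq. The library type was detected as reverse-stranded (ISR), so that reads from a gene and its antisense partner can be told apart. Per the submitters' processing notes, the tools were STAR, Salmon 1.10.3 and DESeq2 with the GRCh38 build. Their roles, the annotation release and the handling of multi-mapping reads are not given in the sources used here. Per the labels, xengsort, which sorts reads of a xenograft into graft and host, gave the percentage of graft reads in each in vivo library. The labels name RUVSeq with the controls as anchors for contamination, but its settings are not given in the sources used here, and no such step was copied. The authors deposited 1 table of Salmon estimated counts per gene, which need not be whole numbers and are not scaled between libraries. Fractional values made up 0.98% to 15.13% of the genes of a library. Salmon divides reads shared by overlapping or near-identical transcripts by a model, so counts of readthrough genes, paralogs and histone genes depend on that division.

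The table held 62754 genes and 10 libraries. Of the gene IDs, 58261 matched GENCODE release 29 on GRCh38, from which gene types, transcript lengths and the 1-based coordinates were taken. The authors' release may differ. Estimated counts were rounded to whole numbers before every test. Scaled counts (CPM) refer to the TMM-scaled total for gene levels and list scores of recurrent against primary tumours, and for gene levels of tumours against controls. They refer to the library total for the culture comparison, the host score, the summed readthrough locus and the floors of genes with no count, unless another total is named. Total counts ran from 20321590 to 39714714 in the tumours, from 1358753 to 4158124 in the controls, and reached 65058642 in the culture. A count of 0 allows up to 3 counts, which is 0.0755 to 0.148 CPM in a tumour and 0.722 to 2.21 CPM in a control. Such limits and the Wilson 95% intervals of shares cover counting error only, since reads without molecular identifiers are not independent molecules. The controls also gave an estimate of the host share of each gene in each tumour. It is the median over the controls of the gene's count per host read, multiplied by the tumour's host reads and divided by the gene's count there. Of the 11726 genes with a mean count over 100, the median host share was 0.0579%, and 66 genes exceeded 10% in some tumour. With 5051 structural small RNA genes kept out of the host reads, a form chosen after seeing the data, the median was 0.518% and 286 genes exceeded 10%. Both forms take the host reads of a library from its count and graft percentage, so they depend on which xengsort read classes entered the counts, which is not given in the sources used here.

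Recurrent and primary tumours were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, default filter on low counts, quasi-likelihood F test, two-sided, no covariates), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE given with an edgeR log2 fold change is the size of that change divided by the square root of its F statistic. Gene lists were tested with limma 3.58.1's camera at its preset inter-gene correlation, adjusted over the lists. Of 34 lists with 729 entries, written from textbook knowledge, 32 had the 5 tested members required. Only the host blood and host microglia and macrophage lists had fewer, with 0 and 4 tested members. Camera was repeated with the correlation estimated from the libraries, and fry (limma) asked whether a list's genes moved one way. The estimated form also takes its degrees of freedom from the libraries and not from the genes, so a call can be lost there at any correlation. The 6 tumours were compared with the 3 controls in an edgeR fit that kept the tumour groups as separate means. The single culture library allowed no test: mean log2(CPM + 1) of the primary tumours was set against the culture, and the median of each list was placed among 10000 random lists of the same size matched on mean expression. Genes were counted at a log2 difference of at least 1 with all 3 primary tumours on one side of the culture. That count and the floor of 5 CPM for the comparison were chosen after seeing the data. A host score, the mean log2(CPM + 1) of tested neuron and oligodendrocyte list members, was correlated with the graft percentage by exact permutation (scipy 1.17.1, Python 3.11.15).

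Groups, tests, gene lists, the alternatives except those named below as added, and the rule for named genes were fixed before the data were examined. For recurrent against primary tumours the rule took up to 12 genes per direction with the largest fold among those past the threshold, with the groups apart, a mean of at least 5 CPM, a host share under 10% and an approved symbol, filled up to 12 by the smallest p. No gene met it as passing, so all 24 are fill-ups. Within each list it allowed the 4 members with the smallest p, and some of these are not reported here. For tumours against controls it took the 8 largest folds per direction among passing genes of at least 20 CPM, and for the culture the 10 largest differences per direction at 20 CPM or more. Alternatives were DESeq2 1.42.0, limma-voom, other size factors, filters and thresholds, covariates (graft percentage, RNA integrity number, library name prefix), removal or subtraction of host counts, and each replicate left out. A correction for transcript length, its references (protein-coding genes only, and camera on log2 CPM), removal of structural small RNAs, host shares computed without them, a host score per count outside structural small RNAs, a robust edgeR form and the RNA integrity and name prefix covariates for lists were added after seeing the data.

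The steps were tested on simulated counts for the tested genes with 200 genes changed. With 3 against 3 tumours (15549 genes), edgeR recovered 57% of the 2-fold and 87% of the 4-fold changes and called 22 unchanged genes. DESeq2 (15928 genes) recovered 69% and 91% and called 40 unchanged genes, and limma-voom (15549 genes) recovered 56% and 86% and called 17. For tumours against controls (15648 genes), edgeR recovered 1% of the 2-fold and 27% of the 4-fold changes. Replicates were checked for duplicates: the chi-square per gene between tumours ran from 37 to 174.4, far above sampling noise.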

Results

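RNA was sequenced from 3 primary U251N tumours, 3 tumours that recurred after LITT, 3 tumour-free control brains and 1 culture of the line. The primary tumours gave 25386280, 25316552 and 39714714 estimated counts and the recurrent tumours 20321590, 25299612 and 24940392. The controls gave 1358753, 1702196 and 4158124, and the culture gave 65058642. Graft reads made up 50.8% ± 11.9 (SD, n = 3) of the reads in primary tumours, 35.1% ± 6.84 (SD, n = 3) in recurrent tumours and 1.93% ± 2.58 (SD, n = 3) in controls. Control replicate 3, at 4.9%, held more than control replicates 1 and 2, at 0.33% and 0.55%. The RNA integrity number was 8.53 ± 0.635 (SD, n = 3) in primary and 8.5 ± 0.361 (SD, n = 3) in recurrent tumours, and lowest at 6.1 in control replicate 2.

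Structural small RNAs, led by RN7SL1, the RNA of the signal recognition particle, took 9.66% ± 4.08 (SD, n = 3) of the counts in primary tumours and 9.69% ± 3.17 (SD, n = 3) in recurrent tumours. In control replicates 1 and 2 they took 92.58% (Wilson 95% interval 92.54 to 92.63) and 89.67% (89.63 to 89.72), against 31.28% (31.24 to 31.33) in control replicate 3. Which read classes of xengsort (graft, both or ambiguous) entered the counts is not given in the sources used here, and these shares depend on it. Across genes, log-scale profiles correlated at 0.957 to 0.974 within the primary group, 0.952 to 0.959 within the recurrent group and 0.942 to 0.967 between the groups. Primary replicate 2 lay apart on the first principal component (29.9% of the variance) at -63.73, with the other primary tumours at -9.29 and -12.29 and the recurrent tumours at 3.78, 40.63 and 40.91.

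**Figure D1:**
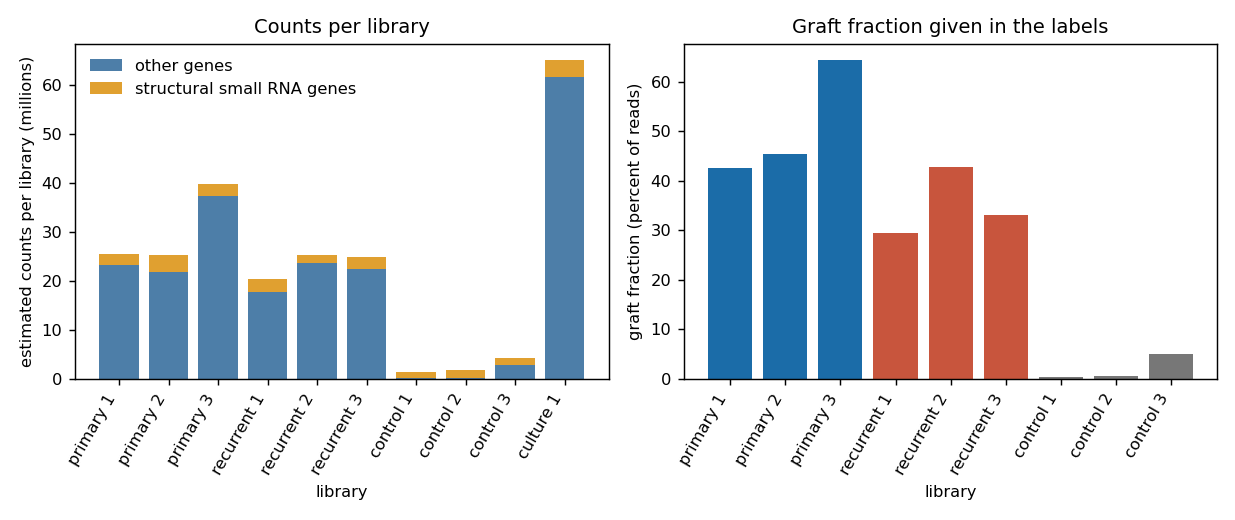
Left, estimated counts of each library, divided into structural small RNA genes and all other genes. Right, percentage of reads assigned to the human graft in the labels, which was 29.44% or more in the 6 tumours and 4.9% or less in the 3 controls.

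The central comparison asked how tumours that grew back after LITT differed from tumours never ablated. At camera's preset correlation, genes of hypoxia and glycolysis, of astrocyte-like glioblastoma cells and of the extracellular matrix were called lower in the recurrent tumours, together with ribosomal proteins. Mitosis, DNA repair, cholesterol synthesis and the genes encoded in mitochondrial DNA were called higher, and with an estimated correlation none of these 8 lists passed. The ribosomal median went from -0.40 to -0.11 without primary replicate 2. The hypoxia call was lost without recurrent replicate 1. The hypoxia, matrix and mitochondrial calls were lost with the graft percentage as a covariate. Mitosis and cholesterol synthesis each lost their call when any one of 3 tumours was left out. DNA repair lost it without recurrent replicate 2 and the mitochondrial list without primary replicate 3. The matrix call stayed with each tumour left out, but its median shrank without primary replicate 1 or 3. Of the matrix genes, biglycan (BGN), a proteoglycan that binds collagen, stood at 71.2 ± 12.9 CPM in primary and 20.1 ± 8.82 CPM in recurrent tumours (SD, n = 3 each). GFAP, the intermediate filament of astrocytes, stood at 534 ± 76 and 304 ± 30.4 CPM (SD, n = 3 each). These 8 list shifts had camera adjusted p from 9.02e-07 to 0.0175 with a preset correlation, and adjusted p from 0.235 to 0.742 with an estimated correlation.

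Gene by gene, edgeR's quasi-likelihood test over 15928 genes called 0 genes higher and 1 lower in recurrent tumours, with 809 higher and 669 lower at an unadjusted p under 0.05. The called gene was PEDS1-UBE2V1 (ENSG00000124208.16, chromosome 20, 50081124 to 50153637, minus strand, GRCh38), annotated as a readthrough of PEDS1, an enzyme of ether lipid synthesis, and UBE2V1, a ubiquitin-conjugating enzyme variant. It fell outside the rule for named genes and was chosen after its values were seen. It stood at 8.54 ± 2.94 CPM (SD, n = 3) in primary tumours and at 0 in all 3 recurrent tumours, at least 195-fold lower against a floor of 3 counts over the group (0.0425 CPM), with an edgeR adjusted p = 0.0215. PEDS1, UBE2V1 and the readthrough gene together stood at 168.2 ± 22 CPM in primary and 189.2 ± 21.7 CPM in recurrent tumours (SD, n = 3 each; exact two-sided permutation p = 0.5, where 3 against 3 cannot go below 0.1). The 2446 genes whose groups did not overlap made up 15.4% of those tested, where chance gives 10%, with 1264 higher and 1182 lower. DESeq2 called 63 genes higher and 42 lower (1688 at an unadjusted p under 0.05), of which 97 had groups that did not overlap, and limma-voom called 0 (1412 at an unadjusted p under 0.05). In edgeR, 32 genes passed without recurrent replicate 1, 3 without primary replicate 1, 4 without primary replicate 3, 2 without recurrent replicate 2, and 0 without primary replicate 2 or recurrent replicate 3.

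None of the 24 genes taken by the fixed rule passed edgeR, with adjusted p from 0.184 to 0.233, and all 24 passed DESeq2, with adjusted p from 2.95e-07 to 0.0115. The rule took only genes whose groups did not overlap, with the smallest edgeR p. Neither their separation nor their passing DESeq2 on the same counts is therefore a test. Among the 12 higher in recurrent tumours, GLDC, the glycine decarboxylase of the glycine cleavage system (chromosome 9, 6532464 to 6645783), had a log2 fold change of 1.66 (SE 0.24), from 11.6 ± 2.1 to 36.5 ± 11.6 CPM (SD, n = 3 each). PRSS12, the serine protease neurotrypsin (chromosome 4, 118280038 to 118353003), differed by 1.02 (SE 0.16), from 60.9 ± 10.5 to 124 ± 10.7 CPM. AMOT, the junction protein angiomotin, differed by 0.69 (SE 0.13), from 162 ± 15.3 to 262 ± 15.9 CPM. The log2 fold changes of the other higher genes were 1.75 for the phosphoinositide 3-kinase adaptor PIK3AP1, 1.61 for the adhesion receptor ADGRG6, 1.44 for the axoneme protein SPAG17, 1.38 for the potassium channel KCNH5, 1.09 for the transporter SLC22A23, 1.07 for the kinase PAK3, 0.88 for ARHGAP26, 0.86 for the desmosome protein PKP2 and 0.81 for the myosin MYO5C.

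Among the 12 lower in recurrent tumours, BGN (chromosome X, 153494939 to 153509554) had the lowest log2 fold change, -1.83 (SE 0.30). COL1A1, a chain of type I collagen (chromosome 17, 50183289 to 50201632), differed by -1.35 (SE 0.28), from 978 ± 367 to 385 ± 102 CPM (SD, n = 3 each), and POSTN, the matrix protein periostin, by -1.01 (SE 0.20), from 828 ± 146 to 410 ± 85.8 CPM. IGFBP3, which binds insulin-like growth factors, differed by -1.43 (SE 0.28), from 431 ± 84.3 to 160 ± 67.8 CPM. LRP1, an endocytic receptor, differed by -1.02 (SE 0.18), from 147 ± 31.9 to 72.6 ± 10.7 CPM, and GFAP (chromosome 17, 44903161 to 44916937) by -0.81 (SE 0.16). The remaining values were -1.65 for the melanocortin receptor accessory protein MRAP2, -1.29 for the ferroxidase HEPH, -1.13 for the adhesion molecule L1CAM, -1.07 for the monoamine transporter SLC29A4, -0.86 for SYTL2, a protein of vesicle transport, and -0.63 for the nuclear receptor coactivator PNRC1.

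**Figure D2:**
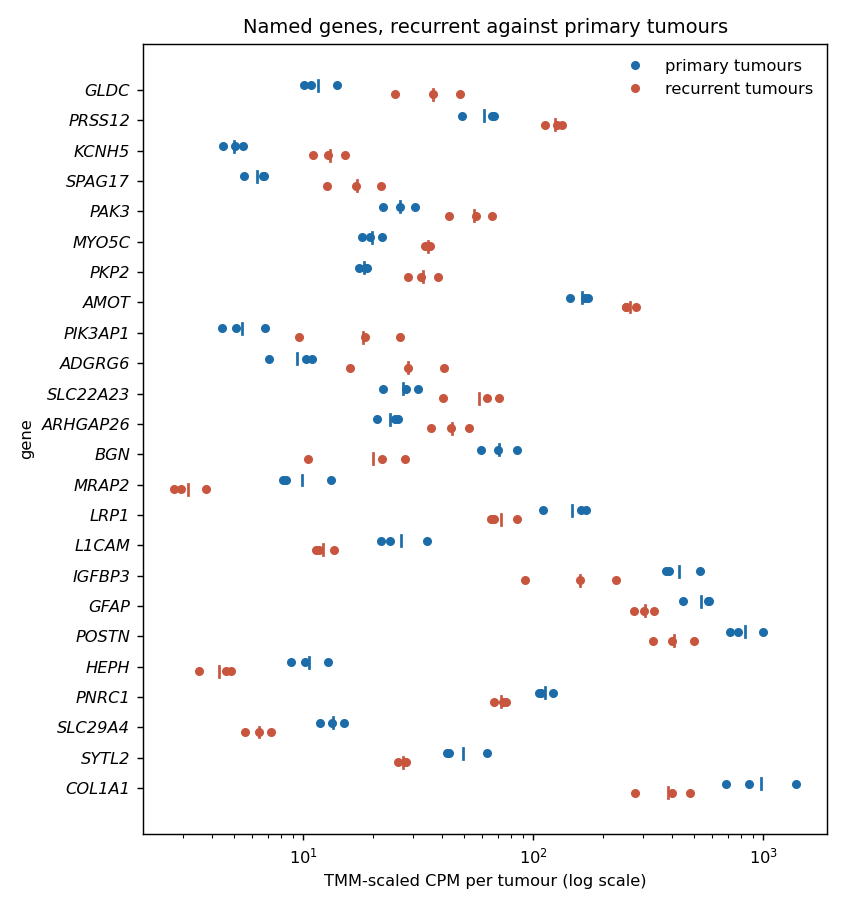
TMM-scaled CPM on a log axis for the 24 genes taken by the fixed rule, with 1 point per tumour and a bar at each group mean. The rule took only genes whose groups did not overlap, and none of the 24 passed edgeR's adjusted threshold.

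Camera at the preset correlation called 13 of 32 lists, 9 lower and 4 higher in recurrent tumours, while 0 lists passed with an estimated correlation (smallest adjusted p = 0.235) or by fry (smallest adjusted p = 0.0771). At a camera p under 0.05 without adjustment the preset form had these 13 lists, heat shock, matrix protease and DNA replication. No list member was called by edgeR over all genes, and in total 18 entries passed when adjusted over the list alone. Of 17 astrocyte-like genes, 17 were lower, with a median log2 fold change of -0.42 (camera adjusted p = 3.27e-05; adjusted p = 0.235 with an estimated correlation). GFAP and FABP7, the brain fatty acid-binding protein (-1.08, SE 0.27), passed adjusted over the list alone. S100B, a calcium-binding protein of astrocytes, differed by -0.75 (SE 0.33). The 8 tested host astrocyte markers, which share members such as GFAP and S100B with that list, had 7 members lower (median -0.41, camera adjusted p = 0.0168; adjusted p = 0.564 with an estimated correlation). This second call was lost without primary replicate 1 (median -0.23, adjusted p = 0.211), primary replicate 3 (0.229), recurrent replicate 2 (0.127) or recurrent replicate 3 (0.204).

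Of 24 extracellular matrix genes, 17 were lower and 7 higher (median -0.16, camera adjusted p = 0.000167; adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone, 5 members passed, among them BGN, POSTN, COL1A1 and the collagen cross-linking oxidase LOX (-1.07, SE 0.22). Its median moved to -0.08 without primary replicate 1, -0.07 without primary replicate 3, -0.39 without primary replicate 2 and -0.31 without recurrent replicate 1. With the graft percentage as a covariate it was -0.04 and the call was lost (camera adjusted p = 0.494). Hypoxia and glycolysis genes were lower in 21 of 24 members (median -0.38, camera adjusted p = 9.02e-07; adjusted p = 0.564 with an estimated correlation), and 0 members passed adjusted over the list alone. P4HA1, a collagen prolyl hydroxylase subunit, differed by -0.68 (SE 0.19), the MYC antagonist MXI1 by -0.99 (SE 0.32), the glycolytic kinase PGK1 by -0.75 (SE 0.29) and the angiogenic factor VEGFA by -0.76 (SE 0.32). Recurrent replicate 1 had the lowest hypoxia score, 5.765 on the log2(CPM + 1) scale against 6.637 to 7.306 in the other 5 tumours, and also the lowest graft percentage. Without it the median was -0.21 and the camera adjusted p 0.093, and with the graft percentage as a covariate the adjusted p was 0.220. Without recurrent replicate 2 the median was -0.83, and with the name prefix as a covariate it was -1.37.

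Ribosomal protein genes were lower in 26 of 26 members (median -0.40, camera adjusted p = 9.02e-07; adjusted p = 0.564 with an estimated correlation), among them RPL18 (-0.42, SE 0.16), and nuclear genes of oxidative phosphorylation in 19 of 22 (median -0.25, camera adjusted p = 0.00204; adjusted p = 0.581 with an estimated correlation). All 22 replication-dependent histone genes were lower (median -0.25, camera adjusted p = 0.0168; adjusted p = 0.823 with an estimated correlation). These 3 lists scored highest in primary replicate 2, where the ribosomal score was 9.634 against 8.789 to 8.962 in the other 5 tumours. That tumour also had the lowest RNA integrity number of the 6, 7.8 against 8.1 to 8.9, and the highest share of structural small RNAs, 14.07% (Wilson 95% interval 14.05 to 14.08) against 6.02% to 12.73%. Without it the median of the ribosomal list was -0.11 (adjusted p = 0.0149), that of oxidative phosphorylation -0.07 (adjusted p = 0.320) and that of the histones 0.10 (adjusted p = 0.146), with the direction turned. The histone call was also lost without recurrent replicate 2 (median -0.14, adjusted p = 0.174), and its median was -0.43 without primary replicate 1 and -0.46 with the graft percentage as a covariate. Short transcripts were high in primary replicate 2: over 13072 protein-coding genes its deviation from the 6-tumour mean correlated with transcript length at a Spearman rho of -0.459, and the log2 fold change between the groups at 0.349, or 0.147 without it. With the length trend removed, chosen after seeing the data, the ribosomal median was -0.26, that of oxidative phosphorylation -0.07 and that of the histones 0.02. The mitochondrial median rose to 0.51 and the matrix median fell to -0.27. These are correlations across genes, which are not independent replicates.

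**Figure D3:**
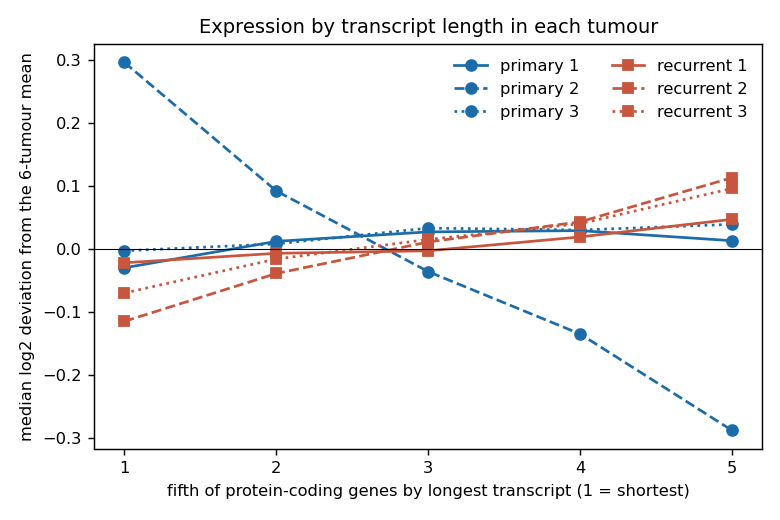
Median log2 deviation of each tumour from the mean of the 6 tumours, for 5 equal groups of 13072 protein-coding genes ordered by the length of their longest transcript. Primary replicate 2 goes from 0.296 in the group of the shortest to -0.288 in that of the longest, and the other 5 tumours stay between -0.115 and 0.113.

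Of the lists that rose by camera, the 13 genes encoded in mitochondrial DNA were higher in 13 members (median 0.22, camera adjusted p = 0.00131; adjusted p = 0.564 with an estimated correlation), and MT-ATP8, a subunit of ATP synthase (0.73, SE 0.18), passed adjusted over the list alone. Mitosis genes were higher in 19 of 25 (median 0.11, camera adjusted p = 0.00985; adjusted p = 0.564 with an estimated correlation), with the kinetochore protein CENPF at 0.51 (SE 0.16), the spindle motor KIF11 at 0.42 (SE 0.15) and the proliferation marker MKI67 at 0.65 (SE 0.26). DNA repair genes were higher in 15 of 21 (median 0.18, camera adjusted p = 0.00845; adjusted p = 0.564 with an estimated correlation), with the checkpoint kinase CHEK1 at 0.39 (SE 0.13). Cholesterol synthesis genes were higher in 14 of 19 (median 0.18, camera adjusted p = 0.0175; adjusted p = 0.742 with an estimated correlation), with the sterol reductase DHCR7 at 0.44 (SE 0.16). Mitosis lost its call without primary replicate 1 (median 0.03, adjusted p = 0.196), recurrent replicate 2 (0.12, adjusted p = 0.0841) or recurrent replicate 3 (0.07, adjusted p = 0.122), and its median was 0.20 without recurrent replicate 1 and 0.19 with the graft percentage as a covariate. Cholesterol synthesis lost it without primary replicate 1 (median 0.12, adjusted p = 0.377), recurrent replicate 2 (0.15, adjusted p = 0.0555) or recurrent replicate 3 (adjusted p = 0.950), where the median turned to -0.01 while camera still tested up. Its median was 0.28 without primary replicate 3, 0.36 without recurrent replicate 1 and 0.43 with the graft percentage as a covariate, and turned to -0.24 with the name prefix as a covariate. DNA repair lost its call without recurrent replicate 2 (adjusted p = 0.0555). The mitochondrial list lost it without primary replicate 3 (median 0.08, adjusted p = 0.229) and with the graft percentage as a covariate (median 0.004, adjusted p = 0.705), and its median was 0.43, 0.37 and 0.13 without primary replicate 2, recurrent replicate 1 and recurrent replicate 3.

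Notch and Wnt genes were lower in 16 of 22 members (median -0.29, camera adjusted p = 0.0168; adjusted p = 0.564 with an estimated correlation), with the Notch target HEY1 at -0.55 (SE 0.15) and the ligand WNT5A at -0.73 (SE 0.24), while the Wnt inhibitor DKK1 stood at 0.92 (SE 0.36). Complement and coagulation genes were lower in 14 of 16 (median -0.21, camera adjusted p = 0.0251; adjusted p = 0.564 with an estimated correlation), with C4B at -0.90 (SE 0.27), while tissue factor (F3) stood at 0.61 (SE 0.26). The first was lost without primary replicate 1 (adjusted p = 0.111), primary replicate 3 (median -0.13, adjusted p = 0.359) or recurrent replicate 3 (0.144), the second without primary replicate 1 (0.212), primary replicate 3 (0.0571) or recurrent replicate 1 (median -0.04, adjusted p = 0.524). With the graft percentage as a covariate the medians were -0.18 and -0.10 and the adjusted p 0.690 and 0.494.

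The library name prefix differs only in recurrent replicates 2 and 3, so with it as a covariate the contrast rests on recurrent replicate 1 against the primary tumours. An arm of 1 tumour gives no test of a group difference, so only the medians are given here. They moved by more than 1.5 times for the hypoxia list, with the low score of that tumour, and for complement (-0.36), the extracellular matrix (-0.09), DNA repair (0.05), oxidative phosphorylation (-0.13), the mitochondrial list (0.03), Notch and Wnt (-0.08) and host astrocytes (-0.04). The median of cholesterol synthesis turned to -0.24.

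The other 19 lists were not called with all 6 tumours and no covariate. Camera's adjusted p was 0.0572 for heat shock, 0.0719 for matrix proteases and invasion, 0.0863 for DNA replication, 0.114 for apoptosis regulators, 0.119 for host neurons, 0.173 for p53 and cell cycle arrest, 0.196 for the unfolded protein and integrated stress responses, 0.284 for mesenchymal glioblastoma and 0.416 for the interferon response. It was 0.749 for progenitor-like glioblastoma, for NRF2 and ferroptosis and for host oligodendrocytes, 0.786 for immediate early genes, 0.805 for angiogenic growth factor signalling and for host endothelium and pericytes, 0.828 for NF-kB and inflammatory cytokines, 0.871 for MHC class I antigen presentation and for TGF-beta and BMP targets, and 0.989 for immune checkpoints. In 6 of these lists the median differed in sign from the mean or the test: NF-kB (median 0.16, mean -0.10), TGF-beta targets (median -0.02, tested up), NRF2 (median -0.01, mean 0.05), host endothelium (median -0.08, mean 0.05), angiogenic signalling (median 0.01, mean -0.06) and immune checkpoints (median 0.01, tested down). Some of these results rest on single tumours or settings. Heat shock (median 0.09) was called higher without primary replicate 3 (0.18, adjusted p = 0.0078) or recurrent replicate 3 (0.10, 0.0371), with the graft percentage (0.24, 0.00529) or the RNA integrity number (0.10, 0.0251) as a covariate, with host-share genes left out (0.08, 0.047) and with the length trend removed (0.20, 0.00113) or in its log2 CPM reference (0.0423). It was not called with an estimated correlation (0.607), by fry (0.418) or in the other settings, and its median was 0.04 without primary replicate 2. The interferon response (median 0.06) was called higher without primary replicate 1 (0.16, 0.0105) or recurrent replicate 3 (0.13, 0.0118). It tested down with the graft percentage as a covariate (-0.12, 0.146), without primary replicate 3 (-0.03, 0.573) and without recurrent replicate 1 (adjusted p = 0.594). Without recurrent replicate 2 the NF-kB list was called lower, with its median turned to -0.27 (0.00654). DNA replication was called higher with the graft percentage as a covariate (0.0459), without primary replicate 3 (0.0447) and with the length trend removed (0.00472). Matrix proteases were called lower and apoptosis regulators higher without primary replicate 2 (0.00397 and 0.00985) and with the length trend removed (0.0174 and 0.0332), and matrix proteases also with host-share genes left out by shares without structural RNAs (0.0387). Some members of these lists passed adjusted over the list alone. The growth factor FGF2 stood at 0.96 (SE 0.19) and the receptor MET at 0.50 (SE 0.13), while IGFBP3 and the receptor ERBB3 (-2.08, SE 0.50) were lower. The receptors PDGFRA, at 0.69 (SE 0.16), and TGFBR2, at 0.60 (SE 0.15), and the cystine transporter SLC7A11, at 0.58 (SE 0.14), were higher, and L1CAM and the ferritin light chain FTL (-0.61, SE 0.17) lower. Of the list members given above besides the 24 genes, DESeq2 called LOX, FGF2, FABP7, PDGFRA, MT-ATP8 and ERBB3, with adjusted p from 0.00142 to 0.0416.

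**Figure D4:**
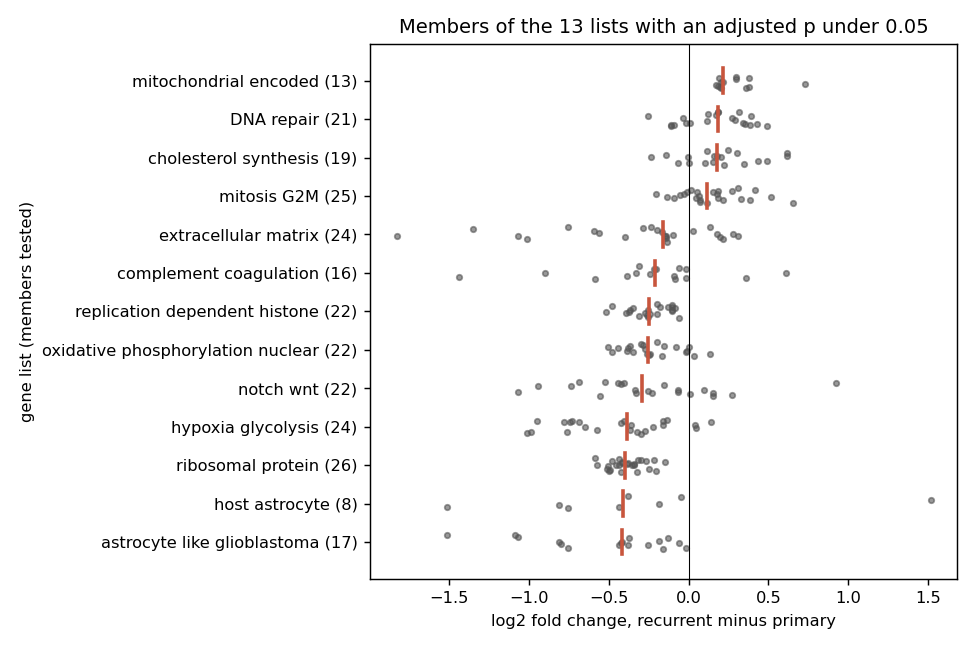
Log2 fold change (recurrent minus primary) of each tested member of the 13 lists called by camera at its preset correlation, with a bar at each list's median and the number of tested members in brackets. All 17 astrocyte-like and all 26 ribosomal protein genes lie below 0 and all 13 mitochondrial genes above it.

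Markers of host cells were also scored, since the dissected tissue held rat brain too. The score of 17 neuron and oligodendrocyte genes was 4.035, 3.71 and 3.947 in the primary tumours, 4.166, 3.976 and 3.895 in the recurrent tumours and 3.438, 3.72 and 4.415 in the controls. These are CPM of totals that consist mostly of structural small RNAs in control replicates 1 and 2, which lowers the score there. With CPM taken of the counts outside structural small RNAs, a form chosen after seeing the data, the score was 6.018, 6.114 and 4.89 in the controls and 3.885 to 4.337 in the tumours. On that scale the neuron list held 34818, 15749 and 1966 CPM in the controls, 1286 to 1928 CPM in the tumours and 903.8 CPM in the culture, which has no host. The oligodendrocyte list held 3851, 1314 and 257.2 CPM in the controls, 198.2 to 268.9 CPM in the tumours and 173.4 CPM in the culture. Over the 6 tumours the score in CPM of all counts correlated with the graft percentage at Pearson's r = -0.332 (exact permutation p = 0.517) and Spearman's rho = -0.543 (exact permutation p = 0.297), the only relation computed in this family besides its alternatives. Without the 2 tumours farthest from the median graft percentage r was -0.199 (exact permutation p = 0.75). With 4 microglia and macrophage genes in place of the score, r was 0.612 (exact permutation p = 0.2). Outside structural small RNAs r was -0.496 over the 6 tumours (exact permutation p = 0.322). GRIA2, a glutamate receptor subunit of neurons, held 2076, 1514 and 1369 counts in the 3 controls and 56 to 493 in the tumours, and its estimated host share reached 100%.

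The tumours were then compared with the tumour-free brains, which show the counts that arise with little or no graft. Among the 8 lower genes taken by the rule, TBR1, a transcription factor of cortical neurons, had a log2 fold change of -11.42 (SE 1.29), the neuronal RNA-binding protein ELAVL4 -10.71 (SE 1.05), the transcription factors NEUROD6 -12.02 (SE 1.59) and MYT1L -11.01 (SE 1.25), the potassium channel KCNC1 -10.89 (SE 1.29) and the NMDA receptor subunit GRIN1 -10.64 (SE 1.51). Their tumour means lay near 0, from 0.0624 CPM for GRIN1 to 0.702 CPM for ELAVL4. The size of these folds is therefore loose, and the SE, computed back from the F statistic, does not measure that. Their counts in the controls were low, from 16 for GRIN1 in control replicate 3 to 387 for KCNC1 in control replicate 1. On the TMM scale they were spread widely between the controls, with TBR1 at 2152, 568 and 24.3 CPM, KCNC1 at 2964, 525 and 31.6 CPM and ELAVL4 at 2313, 628 and 44.4 CPM, so the folds rest mostly on control replicates 1 and 2. No gene list was tested in this comparison. Higher in the tumours were the interferon-induced IFI44L at 2.52 (SE 0.34), with 44.2 ± 6.34 TMM-scaled CPM (SD, n = 6) against a control mean of 7.84 from 1, 3 and 39 counts, the retinal reductase DHRS3 at 1.96 (SE 0.46), the protein-arginine deiminases PADI3 at 1.88 (SE 0.30) and PADI2 at 1.81 (SE 0.33), and the RNA SOX2-OT at 1.49 (SE 0.31). NLGN1, a synaptic adhesion protein, and CGNL1, a junction protein, differed by 1.45 each (SE 0.34 each) and RCAN1, a calcineurin regulator, by 1.42 (SE 0.31). These 8 higher genes held only 1 to 3 counts in control replicate 1 and 3 to 9 in control replicate 2, so their levels there lie near the floor. All 16 genes taken by the rule passed edgeR, with adjusted p from 0.00134 to 0.0302.

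In all, edgeR called 87 genes higher and 844 lower in the tumours of 16389 tested (2914 at an unadjusted p under 0.05), and 526 of the lower genes were protein-coding. ACTR3C, an actin-related protein gene, held 0 counts in the 6 tumours and 40, 16 and 17 in the controls, at least 545-fold lower against a floor of 3 counts over the group (0.0186 CPM; edgeR adjusted p = 0.00696). ACTR3C and EFNA4-EFNA3, a readthrough gene at -11.53 (SE 1.92), have near-identical or overlapping gene copies and are uncertain. DESeq2 called 270 higher and 2010 lower. The split moved with single controls, to 103 higher and 381 lower without control replicate 1, and to 1788 higher and 1242 lower without control replicate 3. With structural small RNAs left out, chosen after seeing the data, it was 53 higher and 522 lower. The scale of this comparison is loose, since TMM factors were 0.0962 and 0.194 in control replicates 1 and 2 against 1.68 to 1.91 in the tumours, and the median log2 fold change over all genes was 0.41.

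Growth in the brain was set against growth in the dish by comparing the primary tumours with the culture. COL1A1 stood at 17.2 CPM in the culture (exact Poisson 95% interval 16.3 to 18.3, counting error only) and 982 ± 402 CPM in the tumours (SD, n = 3), a log2(CPM + 1) difference of 5.67. The small heat shock protein CRYAB stood at 2.06 CPM (interval 1.73 to 2.44) and 98.8 ± 1.6 CPM, and the keratins KRT75 and KRT17 differed by 5.53 and 5.42. TXNIP, a thioredoxin inhibitor induced by glucose, stood at 2158 CPM in the culture (interval 2147 to 2169) and 165 ± 18.4 CPM in the tumours, a difference of -3.71. With 1 culture library, described as an outside reference, the differences have no replicate check and no p-value. COL1A1, KRT75 and the chemokine CXCL12 stood higher still in control replicate 3, at 4261.6, 388.5 and 103.9 CPM of protein-coding counts. The highest values in a tumour or the culture were 1553.8, 152.4 and 35.2. A source other than the graft line was not told apart for these genes. The other genes named for the culture were not among the 30 at 2 times that highest value or more.

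Also higher in the primary tumours were RNA5-8SN2, a ribosomal RNA gene with many copies, by 4.22, the adhesion protein CD34 by 4.16, the transcription factor SP6 by 4.05, the metallothionein MT1E by 3.81, the chemokine CXCL12 by 3.70 and complement C3 by 3.58. Lower were the mitochondrial enzyme OGDHL at -5.04, the transporter ABCA13 at -4.34, the hemidesmosome collagen COL17A1 at -4.20, the spliceosomal RNA gene RNU1-3 at -3.66, the epithelial transcription factors EHF at -3.59 and KLF5 at -3.57, the hyaluronan-binding CEMIP at -3.52, the sodium channel subunit SCNN1A at -3.51 and FAM78B at -3.21. RNA5-8SN2, RNU1-3 and FAM78B had host shares of up to 84.5%, 34.7% and 50.8% when structural small RNAs were kept out of the host reads. Of 11778 genes at 5 CPM or more, 425 were higher and 955 lower by a log2 difference of at least 1 with all 3 primary tumours on one side of the culture. The median over all genes was -0.09, and 0.01 with TMM scaling, under which the immediate early, mesenchymal and angiogenic list medians near 0 turned sign.

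By list, NF-kB and inflammatory cytokine genes were higher in 15 of 16 members in the primary tumours (median 1.57, percentile 100 among 10000 random lists), with CXCL8, a neutrophil chemokine, at 4.58 CPM in the culture and 45.6 ± 22.5 CPM (SD, n = 3) in the tumours. The medians of heat shock (0.78, 20 of 22 higher), astrocyte-like (1.16, 10 of 12), host astrocyte (1.55, 4 of 5), MHC class I antigen presentation (0.58, 13 of 15), cholesterol synthesis (0.54, 14 of 19) and replication-dependent histone genes (0.78, 22 of 22) also lay at percentile 100. Extracellular matrix (0.35), TGF-beta and BMP targets (0.42), ribosomal proteins (0.30), complement and coagulation (0.35) and DNA replication (0.18) lay at percentiles 99.9, 99.88, 99.6, 99.34 and 98.65. Primary replicate 2 stood apart in some of these: its median was 0.02 for the matrix (0.56 and 0.67 in primary replicates 1 and 3), -0.13 for complement and coagulation (0.56 and 0.53), 0.64 for ribosomal proteins (0.07 and 0.17), 1.27 for histones (0.35 and 0.70) and 0.07 for DNA replication (0.17 and 0.32). Genes of mitochondrial DNA were lower in 13 of 13 (median -1.26, percentile 0). Interferon response genes (-0.48), the unfolded protein and integrated stress responses (-0.47) and progenitor-like genes (-0.62) lay at percentiles 0.13, 0.28 and 0.38, with the interferon list at -0.12 in primary replicate 1 (-0.58 and -0.65 in primary replicates 2 and 3) and the progenitor-like list at -1.03 in primary replicate 2 (-0.23 and -0.37 in the other primary tumours), followed by mitosis (-0.34, 2.57) and p53 and cell cycle arrest (-0.40, 3.22). ASNS, the asparagine synthetase of the integrated stress response, stood at 125 CPM in the culture and 33.8 ± 4.3 CPM (SD, n = 3) in the tumours. The other 12 lists lay between percentiles 18.2 and 96.9. The random lists were matched on size and mean expression, not on how far genes vary together. Within lists, the correlation estimated from the tumours was 0.944 for histones, 0.939 for ribosomal proteins and 0.826 for mitochondrial genes. It was 0.334 for NF-kB, 0.225 for heat shock and -0.017 for astrocyte-like genes. Genes that vary together reach percentiles near 0 or 100 more easily. A percentile is therefore a rank and no p-value. CXCL8 and ASNS were chosen after their values were seen.

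**Figure D5:**
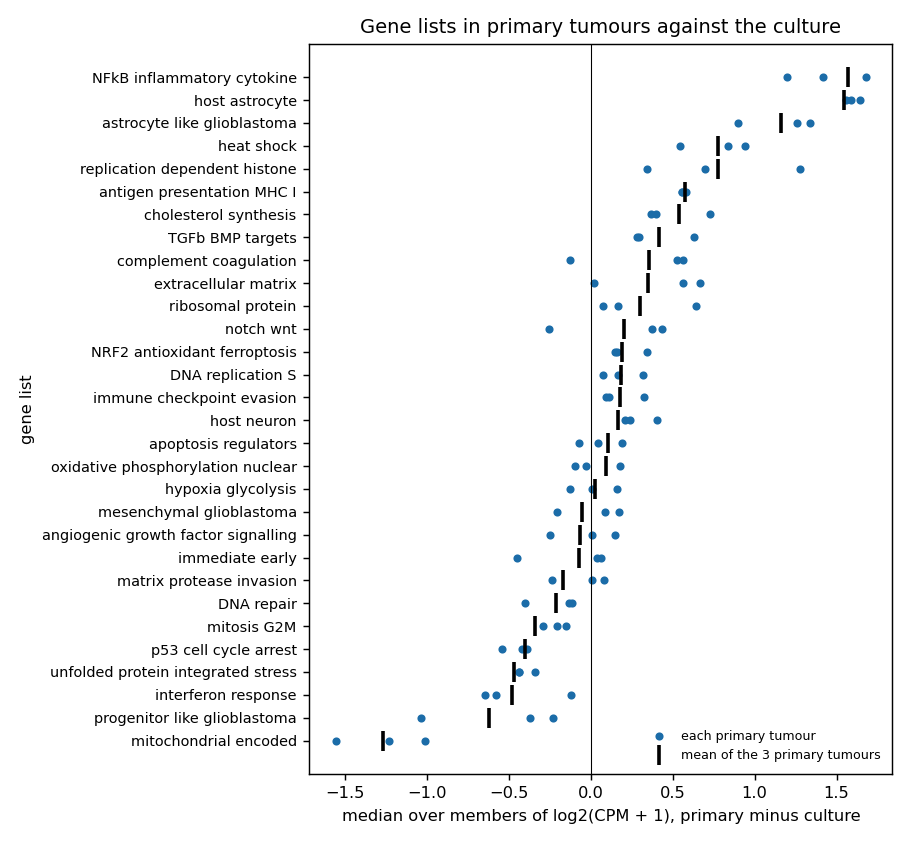
Median over list members of the log2(CPM + 1) difference of primary tumours minus the culture, with 1 point per primary tumour and a black bar for the mean of the 3. The NF-kB list is highest at 1.57 and the genes of mitochondrial DNA lowest at -1.26, with no replicate of the culture.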

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

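The correction for transcript length, the restriction to protein-coding genes and the log2 CPM form run as its references, the robust edgeR form, the removal of structural small RNAs, the host shares computed without them and the RNA integrity and name prefix covariates for lists were chosen only after the result was seen; the cause of a change was not tested unless one is given. For recurrent against primary tumours, the edgeR count of 1 gene stayed at 1 with other size factors, the removal or subtraction of host counts, structural small RNAs left out, protein-coding genes only, the robust form, a threshold of 0.1 and a required log2 fold change of 1. It was 105 by DESeq2 (63 higher, 42 lower), 28 with no filter on low counts (16 higher, 12 lower), 3 with the name prefix as a covariate, 3 with the length trend removed, and 0 by limma-voom, with the graft percentage or the RNA integrity number as a covariate, and at a mean of at least 5 CPM, a filter that removes PEDS1-UBE2V1 itself and so gives it no value. Leaving out single replicates gave 0 to 32 genes. The adjusted p of PEDS1-UBE2V1, which was lower in recurrent tumours in every setting that gave it a value, was 0.117 by limma-voom, 0.108 with the graft percentage, 0.0799 with the RNA integrity number, 0.0705 with the name prefix, 0.157 without primary replicate 2 and 0.0862 without recurrent replicate 3. Over its alternatives it ran from 6.85e-12 to 0.157. The 24 genes taken by the rule kept their direction in every setting run. The rule took only genes whose groups did not overlap, which nearly fixed that outcome, so it is no support. Without the filter on low counts 14 of the 24 passed, and without recurrent replicate 1, 6 did.

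The 13 list calls became 0 with an estimated correlation and 0 by fry, and with single replicates left out 8 to 11 of the 13 kept their call, with 9 to 13 lists called in all. With the graft percentage as a covariate 10 lists were called, 8 of them from the 13, and with the length trend removed 14 were called, 10 of them from the 13. With the name prefix as a covariate 9 lists were called, 5 of them from the 13, but these calls set recurrent replicate 1 alone against the primary tumours and support no group difference. The cholesterol list turned there (median -0.24, camera adjusted p = 0.0151), and mitosis tested down (0.991). At a mean of at least 5 CPM the astrocyte-like median went from -0.42 to -0.27. Removal of genes with a host share over 10% kept all 13. With the RNA integrity number as a covariate 12 of the 13 kept their call, and cholesterol synthesis did not (camera adjusted p = 0.0614). The replication-dependent histone list turned direction with the length trend removed (camera adjusted p = 0.529505) and without primary replicate 2 (0.145764), with a range of 1.81e-07 to 0.174 over single replicates left out.

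For tumours against controls, the 931 genes became 2280 by DESeq2 (270 higher, 2010 lower) and 575 with structural small RNAs left out, and ran from 484 to 3030 with single controls left out. They were 1004 with other size factors and 941 with no filter on low counts. For the culture, 1380 genes became 1305 to 1579. The correlation of the host score with the graft percentage turned to 0.612 with the microglia and macrophage list (exact permutation p = 0.2) and to 0.413 over the 9 in vivo libraries on a logit scale (permutation p = 0.274). With counts outside structural small RNAs, also chosen after seeing the data, it was -0.496 over the 6 tumours and -0.981 over the 9 libraries (permutation p = 0.00074), where the controls stand apart from the tumours. Depth limits the controls most: control replicates 1 and 2 held 100752 and 175821 counts outside structural small RNAs, where tumours held 17734515 or more.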

Other observations

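The readthrough test, the tests of the lists (splits, length, host reads, co-variation) and all tests of control replicate 3, with their bounds, were chosen only after the result was seen. Beyond the genes described above, the stress and identity lists held members with large differences that did not pass edgeR between recurrent and primary tumours. CDKN1A, the p21 inhibitor of the cell cycle, had a log2 fold change of 0.69 (SE 0.21), and the immediate early factors EGR2 and FOSB stood at 1.08 (SE 0.36) and 1.63 (SE 0.60). Among mesenchymal glioblastoma genes, the matrix proteins TGFBI and MGP stood at -0.70 (SE 0.22) and -1.37 (SE 0.44) and the secreted glycoprotein CHI3L1 at -0.88 (SE 0.39). The stress factor DDIT3 stood at -0.74 (SE 0.25), the heat shock protein HSPA4L at 0.50 (SE 0.13), and the transition factors SNAI2 and ZEB1 at -0.58 (SE 0.18) and -0.52 (SE 0.17). None of these passed edgeR over all genes or adjusted over the list alone, and DESeq2 called TGFBI among them (adjusted p = 0.00973).

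The 1 gene called between recurrent and primary tumours, PEDS1-UBE2V1, had an estimated host share of 0.0% and counts of 0 in all 3 controls, which argues against rat reads of the kind the controls hold. The ratio of its log2 fold change with a covariate to that without was 0.996 for the RNA integrity number and 1.0 for the name prefix, weak measures for a gene at 0 in a whole group and with its call lost under both (edgeR adjusted p = 0.0799 and 0.0705), but recurrent replicate 1 held 0 counts at an integrity of 8.8 and the IL prefix, where primary replicates 1 and 3 held 11.93 and 6.88 CPM at 8.9 and the same prefix. A candidate explanation is that Salmon divided the reads of PEDS1 and UBE2V1 differently: the readthrough gene held 3.82% to 6.9% of the summed counts in the primary tumours, and the sum differed between the groups by 0.173 on the log2 scale. That share was 0.65% in the culture of the line, between the primary and the recurrent tumours. In control replicate 3, with 323 and 321 counts of PEDS1 and UBE2V1, the readthrough gene held 0. The primary tumours thus stood highest. A real loss of the readthrough transcript stays open too, since the reads were not analysed here. The 10 splits of the 6 tumours are too few for a share under 0.05: 2 gave as many genes, with 1 gene in the real split and 1 in the highest other.

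The 13 list calls were weighed against transcript length, in parts defined by the outcome of this test: with the trend removed the histone list had a camera adjusted p of 0.529505 and a median that went from -0.22 ± 0.133 to 0.02 ± 0.174 (SD over 20 members), in line with length as its source. The nuclear oxidative phosphorylation and DNA repair lists reached 0.0543 and 0.0613556. Their medians went from -0.25 ± 0.177 to -0.07 ± 0.175 and from 0.18 ± 0.21 to 0.14 ± 0.193 (SD over 22 and 21 members). Length and group cannot be told apart for them because their call ended narrowly with the direction kept. The other 10 stayed at 0.00982367 or less. They were grouped by keeping their call here, so that bound is no further test. It shows only that removing the trend over each gene's longest transcript did not end their calls. The ribosomal median went from -0.40 ± 0.114 to -0.26 ± 0.147 (SD over 26 members). That median was smaller still in size without primary replicate 2, so length stays open as part of its cause. All 13 lists were kept with host-share genes left out, which decides little, because the filter at 10% left most of their members in place. With structural small RNAs kept out of the host reads, the median member's highest host share ran from 0.55% (histones) to 1.82% (mitochondrial genes). Such low shares argue against rat reads of the kind the controls hold as the whole cause. The controls were tumour-free brains, so rat cells present only around a tumour would be missed. The median over the controls also sets aside control replicate 3, as for COL1A1, with 6, 103 and 11848 counts in control replicates 1, 2 and 3. The xengsort read classes behind the shares are not known either. With the graft percentage as a covariate only 8 of the 13 calls stayed, and the medians of the matrix and mitochondrial lists went from -0.16 to -0.04 and from 0.22 to 0.004. The graft percentage averaged 50.8% in primary and 35.1% in recurrent tumours. The groups overlapped, with 42.52% in primary replicate 1 and 42.67% in recurrent replicate 2, and the difference was not tested. An effect of the graft share stays open for the lists lost with that covariate. With an estimated correlation 0 of the 13 held. Genes of a list varying together between single tumours could account for calls where that correlation was high, up to 0.944 for the histones. For the astrocyte-like list it was -0.017, so its loss there (camera adjusted p = 0.235) is not explained by such co-variation. The estimated form also tests on the residual degrees of freedom of the libraries and not on the number of genes. A list can therefore lose its call there at any correlation, and the loss of all 13 cannot tell co-variation from this change. Of the 10 splits, too few for a share under 0.05, 4 gave as many lists, with 13 in the real split and 16 in the highest other (primary replicates 1 and 3 with recurrent replicate 1), and the 3 other splits as large all part primary replicate 2 from the other primary tumours, a structure of the samples. An effect of ablation stays open and was not tested apart from these.

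Control replicate 3, labelled tumour-free, held 2780186 protein-coding counts against 96621 and 168556 in control replicates 1 and 2, and 7400 of 7443 genes expressed in the culture had 10 counts or more, against 990 and 3246. Rat reads misassigned as in the other controls are argued against by 96.65% of these genes having over 4 times the higher count of control replicates 1 and 2, while the ratio of genes detected at all, 1.075, was bounded by the 6920 already detected in control replicate 2 and decides nothing. Carry-over from the other sequenced libraries alone is argued against by 30 genes at 2 times the highest of the 6 tumours and the culture or more, such as COL1A1 at 4261.6 against 1553.8 and KRT75 at 388.5 against 152.4 CPM of protein-coding counts. Its profile correlated across genes at 0.873 to 0.951 with the tumours and 0.858 with the culture, a lowest margin of 0.016 that is in line with graft cells in the tissue, rests on primary replicate 2 and would also arise with carry-over from a tumour. Graft cells, a wrong label, carry-over from a source not analysed here and rat connective tissue adding to conserved collagen and keratin genes stay open, and no biological explanation besides graft cells was tested.

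For tumours against controls, a fit with 2 groups was run on the 84 splits of the 9 libraries into 6 and 3. It is not the fit behind the 931 genes. Only 1 split, the real one, gave as many as its 1081 genes, and the highest other gave 776. All 6 splits that joined control replicates 1 and 2 with a tumour gave 700 to 776 genes, and the rest besides the real one gave 0 or 1. The count therefore follows control replicates 1 and 2 standing apart, a structure of the samples. It cannot exclude chance for a difference of tumours from controls.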
